A study of Mus musculus with 9 samples.

How the data were processed

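Total RNA of B16 cells was sequenced in 9 libraries from 3 groups, a control hairpin and 2 hairpins named shAD4-1 and shAD4-2, with 3 replicates each. Per the labels' protocols the libraries were made with the VAHTS Universal V6 RNA-seq kit. Per the submitters' processing notes the tools were fastp, HISAT2 and HTSeq and the genome build was GRCm39, with no versions given. Whether the counting used strand, and how ribosomal RNA was kept out, are not given in the sources used here, so genes that overlap or run antisense to each other cannot be told apart by their reads. Reads shared by near-identical genes may likewise be divided between them or left out.

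The authors deposited a table of whole-number read counts per gene for the 9 libraries, with 21676 genes named by symbol, and a table of FPKM for the same genes and libraries. Per the file headers the columns name a control and 2 knockdown groups with replicates 1 to 3, and the numbers of the knockdown groups were matched to the numbers of the hairpins in the labels. The deposited FPKM values follow from the deposited counts: for each nonzero value the implied gene length was within 0.001 of a whole number that was the same in all libraries, with the column sum of the count table as the library size. The tables were annotated by the authors with gene ontology terms, which were used here. Adgrl4 was not analysed here. The totals per library, 31.3 to 36.9 M reads, are sums over the genes of the count table.

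Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, which left 13807 genes holding 99.968% of the reads. Libraries were scaled with TMM factors, dispersions were estimated over all 9 libraries with the group as the only term, and each comparison was a contrast tested with glmQLFit and glmQLFTest. P-values were adjusted by Benjamini and Hochberg over all tested genes, at a threshold of 0.05 with no minimum fold change. SEs of log2 fold changes are the fold change divided by the square root of its F statistic. Before the data were examined, 35 gene lists were fixed, of which 34 had tested members. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, with a preset correlation of 0.01 as the main test and an estimated correlation and fry as alternatives, adjusted over the 34 lists of a comparison. Terms among genes at least 2-fold changed in the same direction with both hairpins were tested with the hypergeometric distribution against 12787 tested genes that carry a term, for 2161 terms of 15 to 400 genes.

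The analysis was tested on simulated data. On simulated counts with 200 changed genes per comparison, drawn from genes with a mean of at least 50 reads and made from the means and dispersions of these libraries, edgeR recovered 70% of 1.25-fold, 92% of 1.5-fold and 100% of 2-fold changes for shAD4-1 against control over 13807 genes, with 10 false calls. For shAD4-2 against control it recovered 60%, 90% and 100%, with 13 false calls, and for the difference between hairpins 74%, 92% and 100%, with 7. A simulated list of genes raised 1.25-fold was called by camera in each of the 3 comparisons, and 0 of 34 unchanged lists were. The simulated genes varied independently of each other and most were unchanged. This therefore does not test the preset correlation for lists whose genes move together, such as cytosolic ribosomal proteins, with an estimated correlation of 0.575. Nor does it test scaling, recovery or false calls where most genes change. In the comparisons with control 65% and 69% of the tested genes were called.

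The named genes were chosen by a rule set before the data were examined. Per hairpin these were the 8 largest rises and falls, for both hairpins the 12 largest by the smaller of the 2 changes, and for the difference between hairpins the 5 largest each way, among genes past the threshold whose libraries did not overlap between groups, with at least 5 CPM in the higher group and an official symbol. From each list up to 4 members with the smallest adjusted p-values were taken, and Ccn1, Ccn2, Ankrd1, Yap1, Gnas and Vegfa were always included. Some genes that the rule selects are not reported here. For a group with 0 reads the fold is a bound at 3 reads over the group. For 1 to 3 reads the ratio is given with its exact 95% counting interval, also beside fitted differences between the hairpins.

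Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter or at least 1 CPM in 3 libraries, only the 2 groups compared, the replicate number as a block, each library left out in turn, a fold minimum, glmTreat at 1.5-fold, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with and without a minimum of 1 FPKM in 3 libraries, and protein-coding genes only. After the data were seen 2 were added, leaving out mitochondrially encoded genes and centring the fold changes of each chromosome on 0. Chromosomes came from a RefSeq table of GRCm38.p6, another build than the authors', so it was used only to say which genes share a chromosome and neighbour each other, and GC content came from GENCODE M21 transcripts matched by symbol for 93% of the tested genes.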

Results

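RNA was sequenced from B16 cells, a mouse melanoma line grown in culture, in 9 libraries. Cells carrying a control hairpin (shControl) gave 3 libraries, and cells carrying either of 2 hairpins, shAD4-1 and shAD4-2, gave 3 libraries each. The series title places the study on ADGRL4, an adhesion G protein-coupled receptor, and its relation to tumour dormancy, Gαs-YAP1 signalling and angiogenesis, and the design text describes the 2 hairpin groups as knockdown derivatives with 3 biological replicates a group. The gene counts summed to 31.5, 34.5 and 36.4 M reads in the control libraries, to 36.7, 35.8 and 36.9 M in the shAD4-1 libraries and to 36.4, 31.3 and 31.4 M in the shAD4-2 libraries. P-values in the comparisons measure the spread between these libraries, that is, between replicates of a single derivative line per hairpin. Values per group are reads scaled to library size (CPM) as mean ± SD with n = 3, and log2 fold changes, SEs and adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13807 tested genes.

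The targeted gene, Adgrl4, is not analysed here, so the extent of its knockdown was not measured and the group labels carry no check from it. The first principal component of log2 CPM held 72.5% of the variance and separated the controls, at -63.6 to -66.3, from the shAD4-1 libraries, at 25.9 to 27.3, and the shAD4-2 libraries, at 38 to 39.6. The second held 8.79% and separated the hairpins from each other. The typical variation between replicates was 5.2% (edgeR's biological coefficient of variation). No pair of libraries agreed within sampling noise. Chi-square per degree of freedom ran from 2.99 to 18.1 within groups and from 19.4 to 188 between groups. Control replicate 1 stood apart from the other controls, at 12.4 and 18.1 against 3.44 for their own pair, and without it the genes that differed between the hairpins went from 3777 to 4937. The share of reads from the 13 mitochondrially encoded protein genes was 2.45 ± 0.16% in control, 3.74 ± 0.1% in shAD4-1 and 3.72 ± 0.15% in shAD4-2 libraries (SD, n = 3). Each hairpin library lay above each control library, and the exact permutation test, two-sided, gave p = 0.1 for either hairpin, the smallest value that 3 against 3 libraries allow. In the comparisons with control that shift went along with all the gene groups described below, and its source is not known. Between the hairpins 1 of the 13 genes was called, and their median log2 fold change was 0.03. The shift therefore did not go along with the differences between the hairpins.

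The comparison of shAD4-1 with control asked which transcripts changed under the first hairpin. Among genes with at least 5 CPM in the higher group, antiviral and interferon-induced genes were among those that fell the most: Ifi44 went from 96.4 ± 6.63 to 0.678 ± 0.108 CPM (log2 fold change -7.15, SE 0.12) and Sp100, a nuclear body protein, from 24.4 ± 2.35 to 0.364 ± 0.251 CPM (66.7-fold). Under the same minimum, genes that rose the most included Itga3, the integrin alpha-3 subunit (gene ID 16400), from 0.181 ± 0.0911 to 25.3 ± 2.58 CPM, and Osmr, the oncostatin M receptor, from 0.161 ± 0.0375 to 11.7 ± 0.486 CPM. Further large rises were those of Hspb7, a small heat shock protein (7.91), Fam13c (6.14), Ppp1r3b, which targets a phosphatase to glycogen (5.88), Nostrin, which traffics nitric oxide synthase (5.85), the tetraspanin Tspan2 (5.67) and the amino acid transporter Slc38a3 (5.62), as log2 fold changes. Hspb7, Fam13c, Ppp1r3b and Nostrin stood at no more than 0.161 CPM in any control library, and Hspb7 at 0 in control replicates 2 and 3. The sizes of these rises thus rest on few control reads. The other large falls were those of Mndal, Apol9a, Gbp5, Ifi203, Trim30d and Gbp9, at log2 fold changes between -7.26 and -6.51. These 6 belong to families of related genes. How far their reads were shared with relatives and then divided or left out was not tested, so the size of each is uncertain.

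At an adjusted p of 0.05 in edgeR, 8968 of 13807 genes differed between shAD4-1 and control, 4512 higher and 4456 lower. Most of these differences were small. The median absolute log2 fold change of the called genes was 0.458, a 1.37-fold change, and 827 genes were at least 2-fold higher and 856 at least 2-fold lower. Of 34 tested gene lists, 11 were called by camera with a preset correlation, 8 of them higher (the integrated stress response, endoplasmic reticulum (ER) chaperones, heat shock, G1/S, NRF2, oxidative phosphorylation, YAP/TAZ targets and fatty acid synthesis) and 3 lower (interferon response, antigen presentation and cytosolic ribosomal proteins). With an estimated correlation none of the lists passed in any comparison, and those p-values stand beside each list below.

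The NRF2 list, genes of the response to oxidative stress, rose as a list with shAD4-1, with 16 of 20 members higher and 3 lower (camera adjusted p = 0.000437; adjusted p = 0.345 with an estimated correlation). Hmox1, heme oxygenase, went from 154 ± 5.70 to 348 ± 14.6 CPM (2.26-fold), Txnrd1, thioredoxin reductase, rose 1.97-fold and Srxn1, sulfiredoxin, 1.85-fold. With shAD4-2 the list was not called (adjusted p = 0.202), with 12 members higher and 6 lower. Fatty acid synthesis and storage genes were higher for 13 and lower for 4 of 20 members with shAD4-1 (camera adjusted p = 0.0471; adjusted p = 0.324 with an estimated correlation), and the call was lost without control replicate 1 (adjusted p = 0.0708) and with fold changes centred per chromosome (adjusted p = 0.0667). Plin2, a lipid droplet coat protein, rose 2.52-fold and Fads2, a fatty acid desaturase, 1.61-fold. With shAD4-2 12 members were higher and 3 lower (adjusted p = 0.0752).

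The comparison of shAD4-2 with control asked the same of the second hairpin. Under the same minimum of 5 CPM, interferon-induced genes were again among those that fell furthest, with Ifi44 at 0.252 ± 0.156 CPM (log2 fold change -8.60, SE 0.15) and Trim30a going from 240 ± 20.2 to 1.60 ± 0.245 CPM. Iigp1, an interferon-inducible GTPase, had 607 reads over the 3 control libraries and 2 over the shAD4-2 libraries, a ratio of 0.00354 with a counting interval of 0.000427 to 0.0128. Gbp5, a guanylate-binding protein, had 632 and 2 reads, a ratio of 0.0034 (0.000411 to 0.0123). Itga3 (6.99) and Osmr (6.07) rose as with the first hairpin, and so did Prkg2, a cGMP-dependent protein kinase, from 0.542 ± 0.0553 to 30.8 ± 2.99 CPM, and Crb2, an apical polarity protein (5.75). In edgeR 9522 genes differed, 4724 higher and 4798 lower, with a median absolute log2 fold change of 0.497 among the called genes. At least 2-fold changes numbered 882 higher and 1151 lower. Of the 34 lists 9 were called by camera, 6 higher and 3 lower.

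Cell cycle genes rose as lists with shAD4-2. In the G1/S and DNA replication list 23 of 24 members were higher and none lower (median log2 fold change 0.7; camera adjusted p = 4.7e-08; adjusted p = 0.203 with an estimated correlation). Cdc6, a replication licensing factor, went from 8.01 ± 0.331 to 31.1 ± 1.88 CPM, Mcm4, a helicase subunit, rose 2.93-fold and Rrm2, a ribonucleotide reductase subunit, 2.65-fold. In the G2/M list 17 of 24 members were higher and 3 lower (median 0.42; camera adjusted p = 0.000552; adjusted p = 0.467 with an estimated correlation). Ccnb1, cyclin B1, rose 2.02-fold and Dlgap5, a spindle protein, 2.74-fold, while Mki67, the proliferation marker, fell 1.32-fold. With shAD4-1 the G1/S list was also called, with 16 members higher and 2 lower (median 0.43; camera adjusted p = 0.000422; adjusted p = 0.324 with an estimated correlation). The G2/M list was not, with 10 higher and 11 lower (median 0.03, mean -0.05; camera adjusted p = 0.769). Adjusted over the list alone, 19 and 23 G1/S members were called for the 2 hairpins, and 21 and 20 G2/M members. Over all tested genes 65% and 69% were called, the shares beside which counts of called list members stand here and below.

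**Figure D1:**
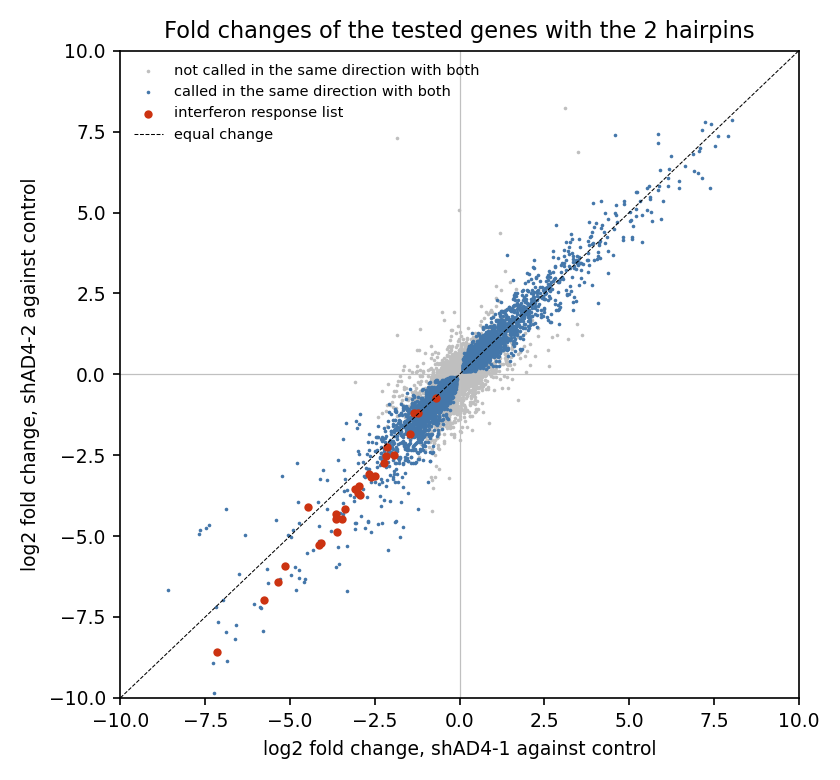
Log2 fold changes of 13807 genes with shAD4-1 (x axis) against those with shAD4-2 (y axis), each against the control libraries; blue points are genes called in the same direction with both hairpins, grey points the others, red points the interferon response list, and the dashed line marks equal change. The points follow the line (r = 0.92), and all 27 interferon response genes lie in the lower left.

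Genes called in the same direction with both hairpins were those on which the 2 comparisons with control met. All 27 tested interferon-response genes fell with both, as did 13 of 15 genes of antigen presentation and 20 of 25 of cytosolic ribosomes, while 17 of 20 ER chaperones and 20 of 26 nuclear genes of oxidative phosphorylation rose. None of these lists was called with an estimated correlation. In all, 7683 genes were called in the same direction, 3876 higher and 3807 lower, and 91 in opposite directions. Of the 7683, 2091 also differed in size between the hairpins. The calls shared were 85.7% of those of shAD4-1. At least 2-fold in both, 652 genes were higher and 704 lower. Independent lists of these sizes would share 1544 higher and 1548 lower genes. In 20 simulations of unchanged groups set against shared controls no gene was called with both, the mean r across genes was 0.503 and the mean covariance 0.0252, against an observed r of 0.92 and covariance of 0.851, a difference in covariance of 0.826. These r values are across genes, which are not independent replicates. The 3 control libraries served both comparisons and could not be divided into parts of at least 2. The simulations gave all groups the mean levels of the control libraries, so they held no difference of the control line itself. Such a difference would shift both comparisons alike, and part or all of the excess in overlap and in r may come from it.

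Among genes with at least 5 CPM in the higher group, the 12 with the largest rises in both included, besides Hspb7, Itga3, Osmr, Fam13c, Ppp1r3b, Nostrin, Slc38a3, Prkg2 and Crb2, the imprinted gene Phlda2, at 0.700 ± 0.174 CPM in control, 28.0 ± 0.436 in shAD4-1 and 29.1 ± 2.43 in shAD4-2 cells, the serine protease Htra3, at 0.766 ± 0.305 CPM in control, 28.5 ± 1.31 in shAD4-1 and 39.3 ± 2.35 in shAD4-2 cells, and the leukocyte-specific actin-binding protein Lsp1, at 0.554 ± 0.192 CPM in control, 18.3 ± 0.240 in shAD4-1 and 18.3 ± 0.879 in shAD4-2 cells. Under the same minimum the 12 with the largest falls were Mndal, Ifi44, Apol9a, Gbp5, Ifi203, Trim30d, Gbp9, Sp100, Iigp1, Trim30a, Apol9b and Oasl2, most of them known as interferon-induced. Oasl2, related to the oligoadenylate synthetases, went from 87.2 ± 7.05 CPM in control to 1.60 ± 0.333 and 0.697 ± 0.246.

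In the interferon response list all 27 tested members fell with both hairpins, over all genes tested and adjusted over the list alone. The median log2 fold change was -2.99 with shAD4-1 and -3.66 with shAD4-2 (camera adjusted p = 6.25e-17 and 3.37e-16; adjusted p = 0.117 and 0.13 with an estimated correlation). Usp18, a negative regulator of interferon signalling, stood at 344 ± 15.5 CPM in control, 9.63 ± 0.781 in shAD4-1 and 5.69 ± 0.606 in shAD4-2 cells (edgeR, Benjamini-Hochberg adjusted p = 1.7e-20 and 4.15e-21). It fell 35.8 and 60.3-fold, Rsad2, the antiviral protein viperin, 8.55 and 11.6-fold, and Oas1a 17.5 and 38.6-fold, with shAD4-1 and shAD4-2 in that order. Oas1a, Ifit3, Trim30a and Trim30d, Apol9a and Apol9b, Gbp5 and Gbp9, Ifi203 and Mndal belong to families of related genes. How far reads were shared within these families was not tested, so their separate values are uncertain. In the antigen presentation list 13 of 15 members fell and 2 rose with both (medians -1.32 and -1.43; camera adjusted p = 8.44e-05 and 0.000227; adjusted p = 0.145 and 0.188 with an estimated correlation). B2m, the light chain of MHC class I, went from 1173 ± 17.2 CPM to 233 ± 14.1 and 195 ± 1.61. Nlrc5, the activator of MHC class I genes, fell 15 and 18-fold and H2-D1, an MHC class I heavy chain with close paralogs, 3.91 and 4.2-fold. Calr, a chaperone that loads class I molecules and also a member of the ER list, rose 1.72 and 1.71-fold. In the NF-kB and cytokine list 6 of 12 members fell and 2 rose with both, and the list was not called (camera adjusted p = 0.162 and 0.202). Its member Csf1, the macrophage growth factor, fell 3.14 and 4.4-fold and Tnfaip3, an inhibitor of NF-kB, 5.02 and 5.41-fold.

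In the ER chaperone list 17 of 20 members rose and 2 fell with both (medians 0.53 and 0.55; camera adjusted p = 6.62e-06 and 2.72e-05; adjusted p = 0.0773 and 0.111 with an estimated correlation). Hspa5, the chaperone BiP, stood at 1012 ± 29.6 CPM in control, 1997 ± 52.0 in shAD4-1 and 2111 ± 63.7 in shAD4-2 cells, and Xbp1, a transcription factor of the unfolded protein response, rose 3.42 and 3.57-fold. In the integrated stress response list 16 of 24 members rose and 4 fell with both (medians 0.55 and 0.44; camera adjusted p = 0.000212 and 0.00917; adjusted p = 0.324 and 0.467 with an estimated correlation). Atf3 rose 3.03 and 2.52-fold, Atf5 2.82 and 3.01-fold and Phgdh, an enzyme of serine synthesis, 1.66 and 1.56-fold, while Ddit3, the factor CHOP, fell 1.37 and 1.87-fold. Of 13 heat shock genes 9 rose and none fell with both (medians 0.52 and 0.56; camera adjusted p = 0.00162 and 0.00208; adjusted p = 0.324 and 0.438 with an estimated correlation), with Hsph1 up 2.41 and 2.49-fold and Hspd1, a mitochondrial chaperonin, 1.48 and 1.58-fold. In these 3 lists 20 and 19, 24 and 21, and 9 and 9 members were called when adjusted over the list alone.

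Nuclear genes of oxidative phosphorylation rose for 20 of 26 members and fell for 3 with both hairpins (medians 0.29 and 0.31; camera adjusted p = 0.000417 and 0.000453; adjusted p = 0.324 and 0.425 with an estimated correlation). Ndufv2, a complex I subunit, rose 1.91 and 2-fold and Cox5b, a complex IV subunit, 1.54 and 1.78-fold, while Cox5a fell 1.72 and 1.42-fold. The mitochondrially encoded genes went the same way, with 12 of 13 called higher for each hairpin and median log2 fold changes of 1.07 and 0.83. Cytosolic ribosomal protein genes fell for 20 of 25 members and rose for 2 (medians -0.42 and -0.43; camera adjusted p = 8.44e-05 and 0.000159; adjusted p = 0.485 and 0.467 with an estimated correlation), with Rps6 lower 1.62 and 1.88-fold and Rpl18 1.77 and 1.89-fold. Adjusted over the list alone, 23 and 24 oxidative phosphorylation genes and 23 and 22 ribosomal protein genes were called.

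**Figure D2:**
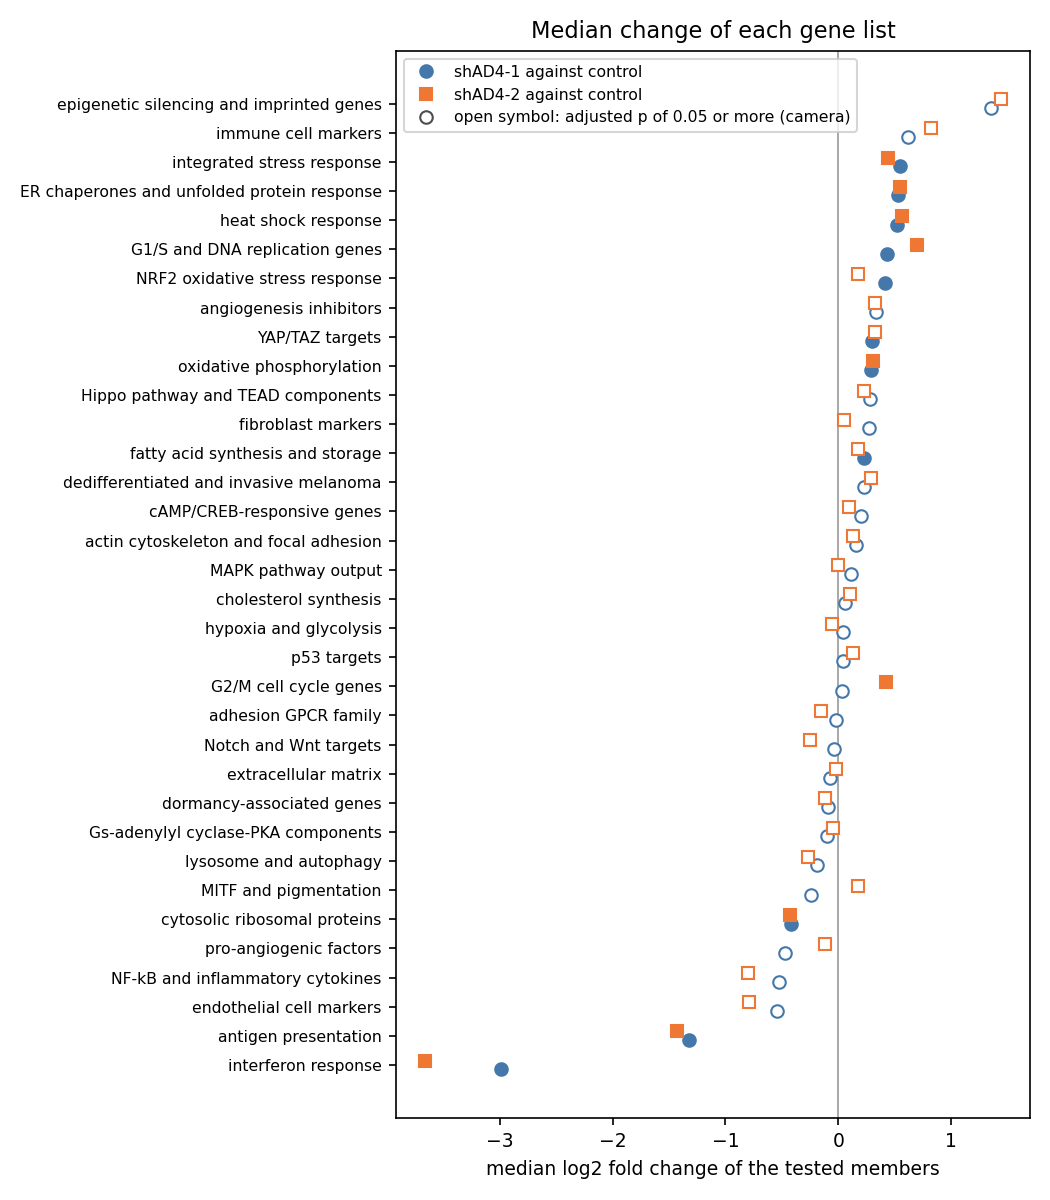
Median log2 fold change of the tested members of each of 34 gene lists (x axis), with shAD4-1 as blue circles and shAD4-2 as orange squares, each against control; filled symbols have a camera adjusted p under 0.05 with the preset correlation. The interferon response list lies furthest from 0, at -2.99 and -3.66.

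The series title names YAP1, Gαs, dormancy and angiogenesis, and lists for these were fixed beforehand. Of 19 tested YAP/TAZ targets 11 rose and 4 fell with both hairpins. The list was called for shAD4-1 (median log2 fold change 0.3; camera adjusted p = 0.0353; adjusted p = 0.324 with an estimated correlation) and not for shAD4-2 (median 0.32; adjusted p = 0.202), and the difference between the hairpins was not called (adjusted p = 0.0719), except with fold changes centred per chromosome (adjusted p = 0.013). Ccn1 (gene ID 16007) stood at 31.5 ± 1.92 CPM in control, 142 ± 4.22 in shAD4-1 and 93.2 ± 5.62 in shAD4-2 cells, and Ccn2 rose 2.15 and 3.2-fold. Ankrd1 had 0 reads over the control libraries and 46 and 40 over the shAD4-1 and shAD4-2 libraries, at least 14.9-fold and 14.3-fold higher at a floor of 3 reads over the control group. Crim1 rose 2.53 and 2.26-fold and Ajuba, an adaptor protein that is also a Hippo regulator, 1.83 and 2.38-fold, while Ccdc80 fell 6.92 and 27-fold. Yap1 itself rose 1.29 and 1.39-fold. In the list of Hippo and TEAD components 15 of 22 members rose and 5 fell with both (camera adjusted p = 0.058 and 0.197). Lats2, a Hippo kinase and a YAP target, rose 1.74 and 1.74-fold, and Sav1, a Hippo scaffold, fell 1.55 and 1.45-fold. Floors and intervals on reads cover counting error only.

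Gnas, which encodes Gαs, fell 1.29 and 1.32-fold, from 1489 ± 90.6 CPM in control to 1155 ± 21.4 and 1125 ± 7.80. Among 19 genes of the Gs, adenylyl cyclase and PKA pathway 5 rose and 7 fell with both, and the list was not called (camera adjusted p = 0.551 and 0.774). Prkar2b, a regulatory subunit of PKA, fell 2.04 and 1.77-fold, Prkaca, a catalytic subunit, fell 1.41 and 1.31-fold, and Pkia, a PKA inhibitor, rose 1.8 and 1.62-fold. Genes that respond to cAMP and CREB went both ways, with 5 higher and 5 lower in both of 17 (camera adjusted p = 0.398 and 0.972). For shAD4-2 their median was 0.09 while their mean was -0.1 and the test pointed down. Ppargc1a, a coactivator of mitochondrial biogenesis, rose 2.68 and 2.75-fold, and Nr4a2 and Crem fell 2.15 and 1.91-fold and 1.49 and 1.69-fold. Of 10 adhesion receptors of the same family as the target 3 rose and 4 fell with both (camera adjusted p = 0.769 and 0.664), among them Adgrl2, higher 1.47 and 1.28-fold, and Adgra3, lower 1.37 and 1.7-fold.

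Of 15 pro-angiogenic factors 7 fell and 3 rose with both hairpins, and the list was not called (medians -0.47 and -0.12; camera adjusted p = 0.4 and 0.317). The chemokine Cxcl1 went from 41.0 ± 2.89 CPM to 2.25 ± 0.203 and 2.64 ± 0.317, and Adm, adrenomedullin, fell 6.11 and 10.1-fold. Cxcl2 had 467 control reads and 2 shAD4-1 reads, a ratio of 0.00417 with a counting interval of 0.000504 to 0.0152. Pdgfa rose 2.05 and 2.26-fold. Vegfa was called higher with shAD4-1 (1.26-fold, edgeR adjusted p = 2.56e-06) and not with shAD4-2 (log2 fold change 0.05, SE 0.04, edgeR adjusted p = 0.334). Of 11 angiogenesis inhibitors 7 rose and 3 fell with both (medians 0.33 and 0.32, means -0.05 and -0.06; camera adjusted p = 0.249 and 0.405). Timp3 rose 2.53 and 1.71-fold and Sema3f 3.04 and 2.76-fold, while Cxcl10, a chemokine induced by interferon, fell 4.61 and 4.27-fold. Of 14 genes associated with dormancy 2 rose and 3 fell with both (camera adjusted p = 0.837 and 0.928). Cdkn1c, an inhibitor of cyclin-dependent kinases, rose from 0.241 ± 0.192 to 4.95 ± 0.542 and 4.57 ± 0.495 CPM, and Bhlhe40 fell 1.7 and 1.67-fold. Adjusted over the list alone, 16 and 19 YAP/TAZ targets, 14 and 15 genes of the Gs pathway, 11 and 10 pro-angiogenic factors and 7 and 9 dormancy genes were called. The tested members numbered 19, 19, 15 and 14 in that order. As 65% and 69% of all tested genes were called, many called members do not by themselves set a list apart.

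**Figure D3:**
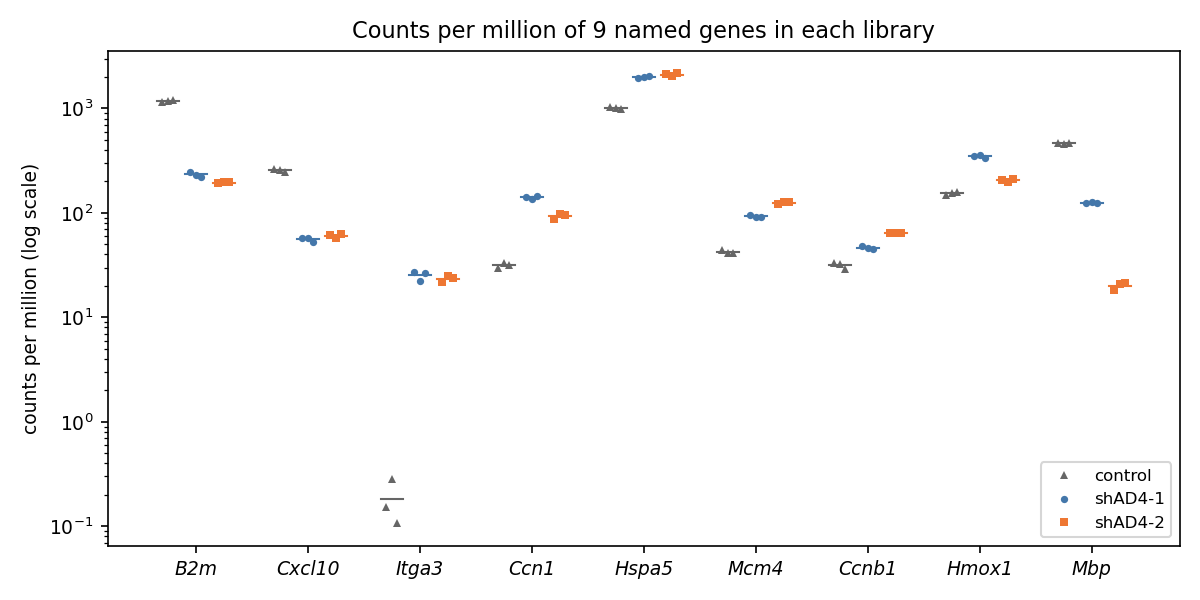
CPM on a log axis of 9 named genes in each of the 9 libraries, with a horizontal line at each group mean; grey triangles are control, blue circles shAD4-1 and orange squares shAD4-2. For B2m the group means are 1173 ± 17.2, 233 ± 14.1 and 195 ± 1.61 CPM (SD, n = 3).

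Melanocyte genes were not called as a list against control with either hairpin. Of 21 genes of MITF and pigmentation 5 rose and 6 fell with both hairpins and 4 were called in opposite directions (camera adjusted p = 0.2 and 0.591). With shAD4-1 5 were higher and 13 lower (median log2 fold change -0.24), and with shAD4-2 11 were higher and 6 lower (median 0.17). The difference between the hairpins was called (camera adjusted p = 0.0296, and 0.769 with an estimated correlation). Mc1r, the melanocortin receptor, fell 2.92 and 2.68-fold and Pax3 rose 1.74 and 2.16-fold. Of 16 genes of dedifferentiated and invasive melanoma 6 rose and 1 fell (camera adjusted p = 0.17 and 0.29, and 0.022 for shAD4-1 with fold changes centred per chromosome), with Nes, the intermediate filament nestin, higher 3.2 and 4.01-fold and Fn1, fibronectin, 2.57 and 2.09-fold. Of 21 genes of the actin cytoskeleton and focal adhesions 7 rose and 3 fell (camera adjusted p = 0.116 and 0.202), among them Itga5, higher 2.61 and 2.25-fold, and Zyx, 2.08 and 1.89-fold. Of 18 extracellular matrix genes 6 rose and 6 fell (camera adjusted p = 0.728 and 0.972), with Fbln1 lower 2.37 and 2.33-fold and Col1a2 higher 6.13 and 8.46-fold. Of 16 genes downstream of MAPK signalling 5 rose and 4 fell (camera adjusted p = 0.355 and 0.886), with the receptor Epha2 higher 17.2 and 16.6-fold, Ccnd1 2.11 and 2.07-fold and Myc 2.07 and 2.16-fold, and Egr1 lower 10.6 and 12.2-fold.

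Metabolic and other lists also went both ways. Median and mean differed in sign for dormancy genes with both hairpins (medians -0.09 and -0.12, means 0.46 and 0.69, with the test down and up), for adhesion receptors (medians -0.02 and -0.15, means 0.15 and 0.01, tests down), for extracellular matrix genes (medians -0.07 and -0.02, means 0.05 and 0.12, tests down) and for Notch and Wnt genes with shAD4-1 (median -0.04, mean 0.4, test up). Glycolysis and hypoxia genes rose for 8 and fell for 10 of 26 members with both (camera adjusted p = 0.769 and 0.583), with Tpi1 higher 2.03 and 1.81-fold and Ldha lower 1.49 and 1.68-fold. Cholesterol synthesis genes rose for 10 and fell for 3 of 24 (camera adjusted p = 0.355 and 0.231), with Insig1, a regulator of that synthesis, at log2 fold changes of 1.07 and 1.18. Lysosome and autophagy genes fell for 14 and rose for 7 of 27 (camera adjusted p = 0.355 and 0.202), with Hexa lower 2.32 and 2.21-fold and Sqstm1, an autophagy receptor, higher 2.02 and 2.07-fold. Targets of p53 rose for 8 and fell for 5 of 22 (camera adjusted p = 0.526 and 0.202), with Mdm2 higher 2.04 and 2.67-fold and Zmat3 1.93 and 1.89-fold. Of 10 Notch and Wnt genes 2 rose with both (camera adjusted p = 0.642 and 0.855), of which Notch1 rose 5.48 and 5.32-fold. Of 6 imprinted genes 4 rose and 2 fell with both (camera adjusted p = 0.234 and 0.264), with Plagl1 higher 3.28 and 3.21-fold and Mest lower 3.39 and 4.39-fold. H19 had 1 read over the controls and 368 and 296 over the hairpin groups, ratios of 359 (counting interval 64 to 14200) and 318 (56.6 to 12600).

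Most markers of other cell types had too few reads to test. Of 14 immune cell markers listed 5 could be tested, none was lower with both hairpins and 2, Lyz2 and Coro1a, were higher (camera adjusted p = 0.234 and 0.202). Lyz2, lysozyme, stood at 0.183 ± 0.101 CPM in control, 2.89 ± 0.532 in shAD4-1 and 4.29 ± 0.192 in shAD4-2 cells, and no tested marker of this list exceeded 4.79 CPM in any library. Of 3 endothelial markers tested 2 fell with both, Eng 2.05 and 1.73-fold and Egfl7 1.46 and 1.89-fold (camera adjusted p = 0.362 and 0.317), and of 3 fibroblast markers 1, Pdpn, rose 2.18 and 2.85-fold (camera adjusted p = 0.179 and 0.317). No keratinocyte marker had enough reads to test, and the highest value was 0.11 CPM.

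The last comparison set shAD4-1 directly against shAD4-2, with the control libraries entering only through filtering, scaling and the estimate of the spread. Cell cycle genes were lower, and oxidative stress and interferon-response genes higher, with shAD4-1 than with shAD4-2. All 24 G2/M genes were lower (median log2 fold change -0.44; camera adjusted p = 4.11e-19; adjusted p = 0.152 with an estimated correlation), as were 20 of 24 G1/S genes (median -0.32; camera adjusted p = 9.2e-13; adjusted p = 0.152 with an estimated correlation). Rrm2 was 1.64-fold, Dlgap5 1.69-fold and Ube2c, a mitotic ubiquitin-conjugating enzyme, 1.57-fold lower. Of 20 NRF2 genes 17 were higher (median 0.32; camera adjusted p = 3.64e-09; adjusted p = 0.255 with an estimated correlation), with Hmox1 1.69-fold and Srxn1 1.32-fold higher. Of 27 interferon-response genes 21 were higher and none lower (median 0.67; camera adjusted p = 1.81e-11; adjusted p = 0.199 with an estimated correlation), Ifit3 by 2.14-fold and Oas1a by 2.2-fold.

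Single genes differed more. Mbp, which encodes myelin basic protein, stood at 462 ± 2.53 CPM in control, 126 ± 0.780 in shAD4-1 and 20.1 ± 1.54 in shAD4-2 cells (edgeR adjusted p = 3.38e-17 for the difference between hairpins), and Fndc3c1 at 65.5 ± 1.84 CPM in control, 15.1 ± 0.368 in shAD4-1 and 1.51 ± 0.601 in shAD4-2 cells. Rbms3, Mcoln3 and Slc44a3 were also higher with shAD4-1, by 3.03-fold, 2.84-fold and 2.37-fold. Oca2, a melanosome transporter, fell to 1.77 ± 0.180 CPM with shAD4-1 and rose to 10.5 ± 1.12 with shAD4-2 from 3.97 ± 0.591 in control, and Mgll, monoglyceride lipase, went the same ways, at 4.39 ± 0.523, 19.6 ± 2.16 and 6.11 ± 0.831 CPM. Grb14, Chadl and Spp1, osteopontin, were lower with shAD4-1 than with shAD4-2 by 2.16-fold, 2.06-fold and 1.99-fold. In edgeR 3777 genes differed between the hairpins, 1933 higher with shAD4-1 and 1844 lower, of which 189 and 44 were at least 2-fold apart, and the median absolute log2 fold change of the called genes was 0.265. Adjusted over the list alone, 24 G2/M, 22 G1/S, 18 NRF2 and 21 interferon-response genes differed, beside 27.4% of all tested genes.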

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

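The tests of interferon genes, of the placing of shifted genes and of library size in this part were chosen after the results were seen, and the tests of other splits, of GC content and length, of chromosome windows and of histone genes before, although chromosomes 10 and 14 were picked after their medians were seen. Genes and lists that differ between the hairpins are those past edgeR's or camera's test of the difference itself, and in edgeR these were 3777 genes. In the 10 splits of the 6 libraries of each of the 3 comparisons, 1 split, the real one, gave as many calls as it, and the highest of the others gave 0, against 8968, 9522 and 3777 genes, but 10 splits are too few to give a share under 0.05. For the genes changed in the same direction by both hairpins, 1 of 100 splits of the 9 libraries, the real one, gave 7683 and the highest of the others 62. Splits that mix control and hairpin libraries widen the spread within groups and so call few genes. The count thus shows that the groups of libraries differ. As each group is a single line, the splits cannot tell an effect of the hairpins from other differences between the lines.

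Among the gene lists 8 differed between the hairpins by camera. As medians of shAD4-1 minus shAD4-2 on the log2 scale, these were G2/M at -0.44, G1/S at -0.32, p53 targets at -0.09 (adjusted p = 0.501 with an estimated correlation), MITF and pigmentation at -0.15 (adjusted p = 0.769 with an estimated correlation), the integrated stress response at 0.14 (adjusted p = 0.463 with an estimated correlation), hypoxia and glycolysis at 0.17 (adjusted p = 0.769 with an estimated correlation), NRF2 at 0.32 and the interferon response at 0.67. The pigmentation call was lost without shAD4-2 replicate 1 (adjusted p = 0.0614).

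Of 257 named genes 31 differed between the hairpins by at least 1 on the log2 scale or were called in opposite directions against control. Given as shAD4-1 minus shAD4-2, the interferon-induced genes among them were Mndal 1.65, Ifi44 1.45, Ifi203 2.01, Trim30d 1.58, Trim30a 1.37, Apol9b 1.33, Oasl2 1.2, Oas1a 1.14 and Ifit3 1.1. Further genes higher with shAD4-1 were Fndc3c1 3.3, Mbp 2.65, Rbms3 1.6, Mcoln3 1.51, Slc44a3 1.25, Ccdc80 1.96, Rgs2 1.53, Slc7a11, the cystine transporter, 1.08, and Hey2 2.89. Genes lower with shAD4-1 were Oca2 -2.56, Mgll -2.16, Grb14 -1.11, Chadl -1.05, Cxcl2 -2.83, Pdgfb -1.05 and Igfbp5 -3.38. Jund 0.4, Asns 0.35, Cdkn1a -0.36, Ube2c -0.65, Pmel -0.72 and Cdk2 -0.58 were called in opposite directions against control, which for Cdk2 ended when each chromosome was centred (-0.04 with shAD4-2). The values of Mndal, Cxcl2, Igfbp5 and Hey2 rest on few reads in the lower group. Igfbp5 had 0 reads in control, 4 with shAD4-1 and 41 with shAD4-2. As ratios of reads with shAD4-1 to those with shAD4-2, Cxcl2 was at 0.121 (2 and 15 reads, counting interval 0.0134 to 0.52) and Hey2 at 8.16 (27 and 3 reads, 2.51 to 42).

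The fall of the interferon-response genes with both hairpins was the largest change of any list. Immune cells in the control cultures stay open, since 0 of the 5 tested markers were lower with both hairpins but none exceeded 4.79 CPM in any library, so that few could have been called lower. Among Ifnar1, Ifnar2, Jak1 and Tyk2 the lowest ratio to control was 0.613, for Ifnar2 with shAD4-2. That argues against a near-complete loss of a receptor or receptor-kinase transcript and leaves a partial one open. Ifnar2 was called lower with both hairpins (log2 fold changes -0.629 and -0.707, edgeR adjusted p = 3.81e-09 and 7.01e-10), as was Tyk2 (-0.254 and -0.251, edgeR adjusted p = 0.000485 and 0.000523). Ifnar1 was called higher with both (0.241 and 0.309) and Jak1 higher with shAD4-1 alone (0.131). An interferon state of the single control line, rather than an effect of the hairpins, cannot be told apart from them, because no other control line was analysed here. The comparison of the hairpin lines used the control libraries only for filtering, scaling and the estimate of the spread. It found 21 of 27 members different, all higher with shAD4-1, so the level also varied between lines that both carry a hairpin. Loss of the target may be a source of the change that was not tested against the control's own state.

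Genes of the same chromosome shifted together, chromosome 10 (709 genes, medians 0.24 and 0.28) and chromosome 17 (0.15 and 0.14) upward with both hairpins, chromosomes 18 (-0.17 and -0.22) and 2 (-0.13 and -0.16) downward with both, and chromosome 14 downward with shAD4-1 against shAD4-2 (454 genes, median -0.16). Against control the chromosome 14 medians were 0.02 with shAD4-1 and 0.16 with shAD4-2, so that difference lay mainly in a rise with shAD4-2. For chromosome 12 they were -0.18 and -0.06, with a difference of -0.11. Random placing was argued against by the spread of medians of 30 neighbouring genes, at least 1.31 times the largest of 1000 shuffled orders in the 3 comparisons. A trend with GC content or transcript length was argued against by the median of chromosome 10 after correction, 0.24 for the hairpin with the smaller value. A difference in chromosome copies between the lines is a candidate explanation, with 91.3% or more of 23 windows along chromosome 10 above 0 for each hairpin, although these windows lie on a chromosome picked for its median. The cell lines may thus differ in more than the hairpin, and centring each chromosome gave 7554 genes called in the same direction with both, of which 6886 were among the 7683.

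Mitochondrially encoded transcripts were higher with both hairpins, by 1.28 and 1.27 percentage points of all reads. Library size was argued against by 4 pairs of a hairpin and a control library with totals within 1% of each other, of which all 4 were higher in the hairpin library, by at least 1.06 points. This test replaced, after its result was seen, a first one on hairpin libraries within the range of the control totals, which left 1 library. More RNA without a poly(A) tail in the hairpin libraries stays open: the 13 histone genes, whose transcripts mostly lack such a tail, had a median of -0.03 with shAD4-1 and 0.63 with shAD4-2 and went both ways. The bound set beforehand, a smaller median below 0, was met by that -0.03 alone and would have argued against it; reading the test as open because members went both ways was decided after the value was seen. An effect of the hairpins on mitochondrial transcripts stays open as well and was not tested apart from it.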

How the results depend on the processing

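Counts of called genes stayed within 1.5 times of the main ones, with the share of higher genes within 10 percentage points of the main one, under other scaling, DESeq2, other filters, limma on FPKM and the 2 alternatives added after seeing the data. A minimum absolute log2 fold change of 1 left 1683, 2033 and 233 genes (shAD4-1, shAD4-2 and their difference, where 81.1% were then higher with shAD4-1) and 1356 with both hairpins, and glmTreat at 1.5-fold left 2060, 2607, 50 and 1719, since these ask for larger changes. Without 1 library the counts ran from 8372 to 9206, 8985 to 9704, 2785 to 4937 and 7125 to 7915. The 24 genes named for both hairpins were picked for large changes in these same data, so stable calls were likely beforehand. They kept direction and call in 1150 of 1150 combinations of gene, comparison with control and alternative. Over all named genes and comparisons 14705 such combinations stayed the same, 830 lost the call, 83 gained one and 4 changed sign. Of the 830, 363 were lost under the fold minimum and 278 under glmTreat. With an estimated correlation 0, 0 and 0 of 34 lists were called, against 11, 9 and 8, and fry, which does not compare a list with other genes, called 30, 32 and 15. Under fry the test of the cAMP/CREB list (median 0.09) and of the Notch and Wnt list (median -0.25) pointed the other way for shAD4-2. Centring each chromosome turned Hsp90aa1 with shAD4-1 to 0.13 and, with shAD4-2, Cdk2 to -0.04, Mmp14 to -0.02 and Tln1 to 0.09. The setting takes the median of a chromosome off the changes of its genes, so changes smaller than that median change sign. The same setting lost the fatty acid call for shAD4-1 (adjusted p = 0.0667) and gained calls for dedifferentiated melanoma with shAD4-1 (0.022) and for the YAP/TAZ difference (0.013). Without control replicate 1 the Hippo list was gained for shAD4-1 (0.0471), and without shAD4-2 replicate 1 or 3 the cAMP/CREB difference (0.0418 and 0.0383). With the replicate number as a block 8833, 9375, 3511 and 7553 genes and 11, 9 and 8 lists were called. Libraries with the same number did not deviate together (r across genes from -0.124 to 0.002, 0 of 9 pairs over 0.1), and 0 libraries correlated best with their own number. The alternatives could give no value for Adgrl4. Depth limits genes with few reads, of which 7869 were not tested.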

Other observations

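All tests in this part were chosen after the main results were seen, except the gene lists. Among the genes at least 2-fold higher with both hairpins, 601 carried an annotation term, and terms of the cell surface and its surroundings were over-represented. The term extracellular matrix held 32 of them against 5.73 expected (hypergeometric test, adjusted p = 1.46e-12), monoatomic ion channel activity 15 against 2.77 (adjusted p = 4.26e-05), growth factor activity 11 against 2.54 (adjusted p = 0.0049) and angiogenesis 21 against 8.55 (adjusted p = 0.0107). Surface terms were also over-represented among the genes at least 2-fold lower with both, with external side of plasma membrane holding 22 against 7.85 (adjusted p = 0.00109), and cell adhesion was so on both sides, with 35 higher genes against 13.1 (adjusted p = 5.75e-05) and 29 lower genes against 12.8 (adjusted p = 0.00235). These tests treat genes as independent. Examples, chosen after their values were seen, were the matrix genes Col9a2 (log2 fold changes 2.56 and 3.01), Ccn4 (2.18 and 2.49) and Sned1 (2.42 and 2.35), the channel genes Chrnb1 (2.97 and 2.95), Cacna1c, a calcium channel (2.17 and 2.81), and Kcnh2, a potassium channel (1.85 and 1.99), and the cytokine Il11 (4.65 and 4.72). Genes with the angiogenesis term that rose included Epas1, the factor HIF-2 alpha (1.91 and 1.99), Hif3a (4.86 and 5.28), Ptk2b (1.99 and 2.62), Epha2 and Notch1. The extracellular matrix list fixed beforehand, which holds collagens, laminins and other matrix genes, was not called.

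Among the genes at least 2-fold lower with both, 587 carried a term, and defense response to virus held 43 against 6.52 expected (adjusted p = 4.81e-21) and cellular response to interferon-beta 24 against 1.65 (adjusted p = 4.81e-21). Ifnb1, interferon-beta itself, fell below the filter. It had 5, 13 and 6 reads in the control libraries, 0, 0 and 4 in the shAD4-1 libraries and 0, 1 and 0 in the shAD4-2 libraries, ratios to control of 0.156 (counting interval 0.0393 to 0.454) and 0.043 (0.00105 to 0.264). Stat2 and Irf9, which are themselves induced by interferon, were at 0.228 and 0.21 and at 0.365 and 0.277 of control with shAD4-1 and shAD4-2. Genes that sense nucleic acids or relay the signal did not move together. Sting1 (log2 fold changes -0.03 and -0.02), Mavs (0.05 and -0.03) and Irf3 (-0.03 and -0.01) were not called in either comparison. Tbk1 was called higher with shAD4-2 alone (log2 fold changes 0.04 and 0.18; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.549 and 0.00532, and 0.0503 for the difference between hairpins). The RNA sensors Ddx58 and Ifih1, members of the interferon response list, fell 4.65 and 6.73-fold and 3.79 and 5.6-fold.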
